A study of Mus musculus with 12 samples.

How the data were processed

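RNA from 12 samples of splenic cDC2, 3 each of L-cDC2, M-cDC2, CLP-cDC2 and CDP-cDC2, was extracted with a column kit and made into libraries with SMART-Seq HT and Nextera XT reagents, per the labels' protocols. Mice were 7 to 8 weeks old and kept free of specific pathogens, per the labels. Groups and replicate numbers were taken from the labels. The labels do not say whether L-cDC2 and M-cDC2 came from the same mice, nor which markers were used in the sort.

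The authors deposited a single table of FPKM (fragments per kilobase of gene length per number of assigned fragments) for 55322 genes. Trim Galore 0.6.7, Trimmomatic 0.39, cutadapt 3.7, STAR 2.7.9a, featureCounts 2.0.1 and DESeq2 1.20.0 are named per the submitters' processing notes, which also list GRCh38 and GRCm38, without the role or order of each. Whether counting used strand is not given in the sources used here. Of 52046 gene identifiers shared with the GENCODE M21 annotation of GRCm38, 1462 had the same chromosome and start as deposited, so coordinates are printed as deposited and their build is not given. The table held 0 mitochondrially encoded genes.

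Depth was recovered from the steps of the deposited FPKM. FPKM times gene length divided by 1000 summed to 1000000 in every library, and all values (100%, tolerance 0.02 steps) were multiples of a step taken as 0.01 read, since the commonest low value was 100 steps. From 44.8 to 53.2% of genes above 0 had whole reads. L-cDC2 replicates 1, 2 and 3 had 35880187, 26543345 and 73732243 assigned reads. M-cDC2 replicates 1, 2 and 3 had 45085981, 49261940 and 50793193 assigned reads. CLP-cDC2 replicates 1, 2 and 3 had 33960731, 45623857 and 42459443 assigned reads. CDP-cDC2 replicates 1, 2 and 3 had 36547370, 56086702 and 40796692 assigned reads. These depths assume that the commonest low value is 1 read. A floor of 3 reads was used, which covers counting error only, since the libraries carry no molecular identifiers.

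Values were analysed as log2(FPKM + 1), so differences understate the change of genes with low values. Genes with FPKM of at least 1 in at least 3 libraries were tested (14538 genes, 10113 protein-coding). limma 3.58.1 (lmFit, contrasts.fit and eBayes with trend, two-sided, R 4.3.3, version 1.17.8 of data.table) fitted all 12 libraries with 4 group means and 8 residual degrees of freedom, and adjusted p-values are Benjamini-Hochberg values over all genes tested in a contrast, called under 0.05. Contrasts were L-cDC2 minus M-cDC2, CLP-cDC2 minus CDP-cDC2, the difference between them, CLP-cDC2 minus L-cDC2 and CDP-cDC2 minus M-cDC2. Lists of at least 5 tested members (33 of 36 lists) were tested with limma's camera at a preset correlation of 0.01, adjusted over lists within a contrast, and again with an estimated correlation and with fry. The neutrophil (2 tested members), mitochondrially encoded (0) and sex-linked lists (2) were too small to test. Single values were compared with exact permutation tests, and overlaps with one-sided hypergeometric tests.

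Groups, contrasts, tests, gene lists, the first set of alternatives below and the rule for named genes were fixed before the data were examined. The rule took the 8 genes with the largest log2 difference in each direction of both lineage contrasts (adjusted p under 0.05, mean of at least 5 FPKM in the higher group, no overlap between libraries). It also took up to 2 called members per list, 6 genes per direction called in both contrasts, 5 per direction in the other contrasts and 20 genes fixed by name. Predicted genes, pseudogenes with a ps suffix and variable segments were not named, and some list members were left out. Some genes taken by the rule are not reported here.

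Alternatives were other pseudocounts, filters and scalings, fits of the 2 groups alone, array weights, replicate blocks, no trend, and each library left out in turn. Restriction to protein-coding genes, voom on recovered reads, removal of trends with GC content and gene length among protein-coding genes (GC known for 99.8% of tested protein-coding genes), removal of CDP-cDC2 replicate 3 and M-cDC2 replicate 3 together, removal of other-cell lists with immunoglobulin and T cell receptor genes, and gene lists under other scalings were chosen after seeing the data. No pair of libraries of one group had identical values (1.27 to 2.24% of values above 0 were equal). On simulated data with 200 changed genes, 2-fold and 4-fold changes were recovered in 48% and 89% of cases for L-cDC2 minus M-cDC2 (14128 genes), 51% and 90% for CLP-cDC2 minus CDP-cDC2 (14147 genes) and 19% and 64% for the difference (14165 genes). For CLP-cDC2 minus L-cDC2 (14114 genes) they were 47% and 88%, and for CDP-cDC2 minus M-cDC2 (14164 genes) 47% and 77%. The changed genes were drawn only from those above a minimum of mean reads, and genes were simulated independently. Recovery of genes with few reads was thus not measured.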

Results

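RNA-seq was performed on type 2 conventional dendritic cells (cDC2), antigen-presenting cells that prime CD4 T cells, sorted from mouse spleen 4 days after an intraperitoneal dose of 5 mg/kg of lipopolysaccharide (LPS), the bacterial outer membrane component sensed by Tlr4. The 12 libraries formed 4 groups of 3. L-cDC2 and M-cDC2 were the tdTomato-positive and tdTomato-negative cells of a fate-mapping line in which Cre expressed from Il7r, the interleukin-7 receptor gene of lymphoid progenitors, switches on tdTomato for good. CLP-cDC2 and CDP-cDC2 were the CD45.2 progeny of wild-type common lymphoid progenitors or common dendritic cell progenitors placed in the bone marrow of CD45.1 B6.SJL mice. The stated question was how similar cDC2 derived from CLPs and L-cDC2 are. Depth recovered from the FPKM values ran from 26543345 assigned reads in L-cDC2 replicate 2 to 73732243 in L-cDC2 replicate 3. Of the table's genes, 14538 of 55322 genes were tested. Each library had 12860 to 13892 genes at 1 FPKM or more. Xist, the X-inactivation RNA of female cells, averaged 5.76, 5.53, 8.89 and 7.21 FPKM in L-, M-, CLP- and CDP-cDC2 and differed in neither lineage comparison (limma adjusted p = 0.91 and 0.43). CDP-cDC2 replicate 3 stood apart at -50.6 on the second principal component and M-cDC2 replicate 3 at -40.5 on the third. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

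L-cDC2 and M-cDC2 were compared first, and the genes that rose furthest in L-cDC2 were those of B cells, plasma cells and cytotoxic lymphocytes. Igkc, the kappa light chain constant region (ENSMUSG00000076609, chromosome 6 from 70703419 to 70703950), stood at 1023 ± 304 FPKM in L-cDC2 (SD, n = 3) against 14.9 ± 10.8 in M-cDC2, a log2 difference of 6.17 ± 0.86 (SE, limma adjusted p = 0.0013). Gzma, a granule protease of NK cells and cytotoxic T cells (ENSMUSG00000023132, chromosome 13 from 113230359 to 113237515), stood at 110.0 ± 22.2 against 0.39 ± 0.20 FPKM, a difference of 6.31 ± 0.49 (SE, limma adjusted p = 9.1e-06). Nkg7, a cytotoxic granule membrane protein, rose by 5.92 from 0.44 ± 0.31 to 85.8 ± 18.1 FPKM, and Cd79a, a signalling chain of the B cell receptor, by 5.35 from 0.34 ± 0.23 to 53.5 ± 3.72 FPKM. The light chain joining and constant segments Igkj4 (7.18), Igkj5 (6.26), Igkj1 (5.48), Iglj1 (6.88), Iglj2 (6.42) and Iglc1 (6.49) rose in log2 units as well. Igkj4 is 38 bases long, its mean of 0.80 FPKM in M-cDC2 lies under the 1.55 to 1.75 FPKM that 3 reads are worth there, and its fitted log2 difference ran from 5.35 to 9.05 across settings. Without a filter on low values the call of Igkj4 was lost (adjusted p = 0.064). The kappa segments share their span with Gm30211, Iglj2 lies inside Iglc2 and the lambda genes are near-identical copies, so their single values are uncertain. Of the B cell list 10 of 13 tested members rose (13 adjusted over the list alone), with camera adjusted p = 3.7e-28, and adjusted p = 0.0053 with an estimated correlation. Of the NK cell and ILC list 9 of 12 rose (10 adjusted over the list alone), among them the granule proteins Gzmb (3.61) and Prf1 (2.42) and the chemokine Xcl1 (3.26), with camera adjusted p = 4.0e-25, and adjusted p = 0.0068 with an estimated correlation. Of the plasma cell list 5 of 6 rose, namely Jchain, Mzb1 (3.37), Derl3, Ighg2c (3.84) and Iglv1 (5 adjusted over the list alone), with camera adjusted p = 1.8e-11, and adjusted p = 0.008 with an estimated correlation. Of the T cell list 5 of 7 rose, namely Trbc1, Trbc2 (3.14), Cd247, Lck and Cd2 (3.11) (6 adjusted over the list alone), with camera adjusted p = 2.5e-12, and adjusted p = 0.0023 with an estimated correlation. Jchain, Derl3, Iglv1 and Cd247 were singled out after their values were seen. The call of Igkj5 was lost without L-cDC2 replicate 1, 2 or 3 or M-cDC2 replicate 2 or 3 (adjusted p up to 0.11).

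Lymphoid progenitor genes also rose in L-cDC2. Ly6d, a surface marker of lymphoid-committed progenitors (ENSMUSG00000034634, chromosome 15 from 74633905 to 74635469), stood at 40.1 ± 6.41 FPKM in L-cDC2 against 0.87 ± 0.81 in M-cDC2, a log2 difference of 4.55 ± 0.45 (SE, limma adjusted p = 8.5e-05). Tcf7, a transcription factor of T cell and innate lymphoid development, rose by 1.25 from 2.26 ± 0.17 to 6.76 ± 0.54 FPKM, and Il7r, the gene that drives Cre in this line, by 0.79 from 0.95 ± 0.21 to 2.39 ± 0.59 FPKM (adjusted p = 0.039). Of the lymphoid progenitor list 5 of 11 tested members rose, namely Il7r, Ly6d, Tcf7, Gata3 and Cd7 (5 adjusted over the list alone), with camera adjusted p = 3.7e-07, and adjusted p = 0.0076 with an estimated correlation. Gata3 and Cd7 were named after their values were seen. The same libraries carried the B, plasma, NK and T cell genes above, cells in which several of these members are known to be expressed. The T cell kinase Lck rose by 2.84, Mir8119, a microRNA gene inside Lck on the same strand, by 3.05, and Gal, the neuropeptide galanin, by 1.99. S1pr1, a receptor for egress into lymph, rose by 1.77. The call of Il7r was lost without L-cDC2 replicate 1, 2 or 3, M-cDC2 replicate 1, 2 or 3, CLP-cDC2 replicate 1 or 3 or CDP-cDC2 replicate 2 (adjusted p up to 0.32).

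Myeloid and cDC1 genes were lower in L-cDC2 than in M-cDC2. Lyz2, the lysozyme of myeloid cells (ENSMUSG00000069516, chromosome 10 from 117113236 to 117118226), stood at 106 ± 6.18 FPKM in L-cDC2 against 274 ± 11.3 in M-cDC2, a log2 difference of -1.36 ± 0.24 (SE, limma adjusted p = 0.0087), and shares sequence with its paralog Lyz1. The chemokine Ccl9, the leukotriene B4 receptor Ltb4r1 and the C-type lectins Cd209a and Clec7a fell by 2.06, 1.74, 1.32 and 1.24 on the log2 scale. Kcne3, a potassium channel subunit, fell by 1.80, Wfdc17 by 1.63, Mcub, a subunit of the mitochondrial calcium uniporter, by 1.58, Rab7b by 1.51, Ifi205 by 1.42, Aif1 by 1.38 and Adgre4 by 1.26. Of the cDC1 list, markers of the cross-presenting subset, 5 of 11 tested members fell, namely Xcr1 (-1.10), Clec9a, Irf8 (-0.95), Gcsam and Naaa (-1.28) (7 adjusted over the list alone), with camera adjusted p = 1.6e-12, and adjusted p = 0.0053 with an estimated correlation. Of the list of inflammatory cDC2 and monocytes 3 of 11 fell, namely Ccr2, Cd14 (-1.23) and Lyz2 (5 adjusted over the list alone), with camera adjusted p = 6.5e-06, and adjusted p = 0.0068 with an estimated correlation. Clec9a shares its span with Clec1b and Irf8 its span with Galnt2l. The C-type lectin list (5 members lower, namely Clec4a3, Clec4b1, Clec7a, Clec9a and Cd209a, with Mgl2 higher, of 17, and 7 lower and 2 higher adjusted over the list alone) passed only with the preset correlation (adjusted p = 0.079 with an estimated correlation). The cytokine list did likewise (3 of 18 lower, namely Il1b, Ccl6 and Ccl9, 5 adjusted over the list alone, adjusted p = 0.079 with an estimated correlation). Clec9a, Ccr2, Clec4a3, Clec4b1 and Ccl6 were named after their values were seen. The MHC class II (adjusted p = 0.21 with an estimated correlation), myeloid progenitor (0.12), ribosomal protein (0.36), oxidative phosphorylation (0.35) and glycolysis lists (0.36) in the lower direction, and the cell cycle (0.35) and Notch2-dependent cDC2 lists (0.25) in the higher, also passed with the preset value alone. Among them Lyz2 of the myeloid progenitor list and H2-DMb1 of the MHC class II list (-0.52) were called. After quantile normalization the calls of MHC class II (adjusted p = 0.17, median from -0.15 to 0), myeloid progenitor (0.067) and glycolysis (0.14) were lost. The calls of the Notch2-dependent and glycolysis lists were lost without M-cDC2 replicate 3 (adjusted p = 0.094 and 0.11). Glycolysis lost it also without L-cDC2 replicate 2 (0.062) or M-cDC2 replicate 2 (0.059), and that of the myeloid progenitor list without L-cDC2 replicate 1 (0.10). The call of Kcne3 was lost without L-cDC2 replicate 1 or 2 or M-cDC2 replicate 1 or 2 (adjusted p up to 0.12). Ltb4r1 lost its call without L-cDC2 replicate 1 or 2 or M-cDC2 replicate 1 or 3 (up to 0.092). Ifi205 lost its call without L-cDC2 replicate 1 or 2 or M-cDC2 replicate 1 or 2 (up to 0.16). Cd209a lost its call without L-cDC2 replicate 1, 2 or 3 or M-cDC2 replicate 1 or 2 (up to 0.11). The call of Irf8 was lost without L-cDC2 replicate 1, 2 or 3 or M-cDC2 replicate 1, 2 or 3 (adjusted p up to 0.19). H2-DMb1 lost its call without L-cDC2 replicate 1, 2 or 3, M-cDC2 replicate 1, 2 or 3, CLP-cDC2 replicate 1, 2 or 3 or CDP-cDC2 replicate 2 (up to 0.27). Lyz2 lost its call without L-cDC2 replicate 2 or 3 (up to 0.072). Cd14 lost its call without L-cDC2 replicate 2 or 3 (up to 0.056). The call of Clec7a was lost without L-cDC2 replicate 2 (adjusted p up to 0.07) and that of Mgl2 without L-cDC2 replicate 1 or 3 or M-cDC2 replicate 1, 2 or 3 (up to 0.086).

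In all, 188 genes rose and 64 fell in L-cDC2 (limma on log2(FPKM + 1), adjusted p under 0.05), of which 103 and 59 were protein-coding, and 1201 genes had an unadjusted p under 0.05. The 3 and 3 libraries did not overlap for 19.4% of genes, where chance gives 10%. Of the cDC2 identity list Mgl2 rose and Cd209a fell, 2 of 20 members, 3 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.19). Of the genes fixed by name Flt3, Sirpa, Itgam, Irf4, Klf4, Zeb2, Esam, Cd4, Clec4a4, Clec12a, Clec10a, Ly6c2, Siglech, Tcf4, H2-Ab1 and Ccr7 did not pass, at log2 differences from -0.50 (Clec12a) to 0.51 (Ly6c2) and adjusted p from 0.25 to 0.99. With array weights Clec10a, H2-Ab1 and Clec12a did pass. Without members of the other-cell lists and all immunoglobulin and T cell receptor genes, 85 genes rose and 44 fell. Of the called genes 74.6% were higher, and 64.4% after quantile normalization. With array weights 538 rose and 300 fell. With FPKM of at least 5 in at least 3 libraries 84 rose, and without a filter on low values 35 fell. Without CDP-cDC2 replicate 3 and M-cDC2 replicate 3, 167 rose and 59 fell. The counts dropped to 78 higher and 32 lower without L-cDC2 replicate 1, 78 and 18 without replicate 2, and 80 and 29 without replicate 3, and the lower count to 30, 29 and 38 without M-cDC2 replicate 1, 2 and 3. Calls were lost with a pseudocount of 0.1 for Ltb4r1, Mgl2 and Gal, with a pseudocount of 5 for Il7r, without a filter on low values for Igkj4, Igkj5, Kcne3, Ltb4r1, Ifi205, Cd209a, Mgl2, Lyz2, H2-DMb1, Il7r and Irf8, after quantile normalization for Il7r and with TMM factors for Il7r. They were also lost with only the 2 groups in the fit for Il7r, without the trend for H2-DMb1 and Irf8, among protein-coding genes with GC and length trends removed for Il7r, without CDP-cDC2 replicate 3 and M-cDC2 replicate 3 for Igkj5, Ltb4r1, Mgl2 and Irf8 and without the other-cell lists for H2-DMb1 and Il7r.

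CLP-cDC2 were next compared with CDP-cDC2, the progeny of the 2 progenitors in the same kind of recipient. Ly6d was again higher in the cells of lymphoid origin, at 43.0 ± 23.2 FPKM in CLP-cDC2 (SD, n = 3) against 2.296 ± 1.58 in CDP-cDC2, a log2 difference of 3.76 ± 0.45 (SE, limma adjusted p = 4.5e-04). Phgdh, the first enzyme of serine synthesis (ENSMUSG00000053398, chromosome 3 from 98220486 to 98247306), stood at 73.9 ± 7.39 against 17.7 ± 7.62 FPKM, a difference of 2.07 ± 0.22 (SE, limma adjusted p = 1.7e-04). Cox6a2, a cytochrome c oxidase subunit, rose by 2.95 with a wide spread (27.4 ± 24.9 FPKM), Tdgf1, a Nodal co-receptor, by 1.95, Gal by 2.27, Lck by 1.92, Mir8119 inside it by 1.91 and Tcf7 by 1.18. Il7r rose from 0.91 to 2.81 FPKM. Ly6d and Cox6a2 are also members of the plasmacytoid dendritic cell list (12 tested), of which Zeb2 and Irf7 fell, and that list was not called. Plasmacytoid dendritic cells in the sort were not tested as a source of Ly6d and Cox6a2. The processed pseudogene RP23-92D22.3, whose reads cannot be told apart from those of its parent gene, rose by 3.18. Lymphoid progenitor members Il7r, Ly6d and Tcf7 rose (3 of 11, 4 adjusted over the list alone). The list passed only with the preset correlation (adjusted p = 0.14 with an estimated correlation) and was lost without CDP-cDC2 replicate 1 (adjusted p = 0.066) and after quantile normalization (adjusted p = 0.075). Xcl1 averaged 1.95 ± 1.13 FPKM in CLP-cDC2 and was 0 in every CDP-cDC2 library. B cell genes Cd79b, Ms4a1, Fcer2a, Blk and Fcrla rose (5 of 13, 5 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.23) and without CLP-cDC2 replicate 2 (0.16), the library with 429 FPKM of Igkc against 20.1 and 28.5 in its 2 sister libraries. Cd79b, Ms4a1, Fcrla and Irf7 were named after their values were seen. The cDC1 list moved the opposite way to the reporter cells, with Xcr1 (0.65), Clec9a (0.80), Irf8 (1.10), Cd8a, Cd36 (0.99) and Gcsam (1.51) higher in CLP-cDC2 (6 of 11, 7 adjusted over the list alone, camera adjusted p = 1.0e-04, and adjusted p = 0.048 with an estimated correlation).

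Proliferation genes were higher in CLP-cDC2. Of the cell cycle list 23 of 34 tested members rose (28 adjusted over the list alone, camera adjusted p = 4.3e-17, and adjusted p = 0.048 with an estimated correlation), among them the mitotic kinase Cdk1 at 34.7 ± 3.68 against 16.6 ± 2.31 FPKM, a log2 difference of 1.02 ± 0.15 (SE, limma adjusted p = 0.0012), and Cdc20, an activator of the anaphase-promoting complex (0.90). Of the nuclear genes of oxidative phosphorylation 16 of 40 rose (26 adjusted over the list alone), among them the ATP synthase genes Atp5c1 (0.49) and Atp5g3 (0.66). Of the ribosomal protein list 4 of 48 rose, namely Rpl15 (0.40), Rps16 (0.39), Rps18 and Rps20 (3 adjusted over the list alone). After quantile normalization Rpl15 stood at 0.21, Rps16 at 0.19 and Atp5c1 at 0.31, and none of them was called (adjusted p up to 0.13). The calls of both lists were lost with an estimated correlation (adjusted p = 0.14 and 0.29). The cholesterol synthesis list with Fdps (0.69) and Msmo1 (0.62) and the erythroid and platelet list with Car2 (0.86) passed with the preset correlation only (adjusted p = 0.30 and 0.25 with an estimated correlation). Adjusted over the list alone, 2 of 20 and 1 of 5 members rose in them. Their calls were lost without CDP-cDC2 replicate 1 (adjusted p = 0.14 and 0.11). Cholesterol synthesis lost it also without CDP-cDC2 replicate 2 (0.13) or CLP-cDC2 replicate 1 (0.23) and that of the erythroid list without CDP-cDC2 replicate 3 (0.059) or CLP-cDC2 replicate 2 (0.11). Rps18 and Rps20 were named after their values were seen, as was Cd8a above. Without CLP-cDC2 replicate 2 the call of Atp5g3 was lost (adjusted p = 0.0505) and that of Rpl15 (0.0547). Rps16 lost its call without CLP-cDC2 replicate 1 or 2 (up to 0.067). Fdps lost its call without CLP-cDC2 replicate 1 or 2 or CDP-cDC2 replicate 3 (up to 0.087). Car2 lost its call without CLP-cDC2 replicate 3 or CDP-cDC2 replicate 2 (up to 0.064).

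Genes of myeloid identity, maturation and inflammation were lower in CLP-cDC2 than in CDP-cDC2. Lyz2 stood at 66.7 ± 32.6 FPKM against 476 ± 69.8, a log2 difference of -2.91 ± 0.24 (SE, limma adjusted p = 3.4e-05), with its paralog Lyz1 at -3.28. Cd209a (ENSMUSG00000031494, chromosome 8 from 3793397 to 3798984) stood at 13.8 ± 3.19 against 109.6 ± 46.5 FPKM, a difference of -2.85 ± 0.25 (SE, limma adjusted p = 4.3e-05). Mefv, the pyrin inflammasome sensor, fell by 3.42 on the log2 scale, Apol7c, an apolipoprotein L of dendritic cells, by 2.97, Ocstamp, a cell fusion protein, by 2.62, Pla2g7, an enzyme that degrades platelet-activating factor, by 2.60, Clec7a by 2.49, Adgre4 by 2.11, Ltb4r1 by 2.01 and Wfdc17 by 1.42. The unnamed microRNA gene ENSMUSG00002076463, which lies within Ppp2ca on the opposite strand, fell by 3.74, and the counting is not stated to use strand. Of the maturation and migration list 13 of 23, 20 adjusted over the list alone fell (camera adjusted p = 2.8e-13, and adjusted p = 0.012 with an estimated correlation), among them the lymph node homing receptor Ccr7 at 14.9 ± 2.62 against 36.6 ± 1.26 FPKM, the NF-kB subunit Relb (-1.05), Cacnb3 (-1.96) and the costimulator Cd40 (-0.81). Of the cDC2 identity list 10 of 20, 12 adjusted over the list alone fell (camera adjusted p = 2.6e-07, and adjusted p = 0.048 with an estimated correlation), among them the signal-regulatory receptor Sirpa (-1.33), Cd4 (-1.94), Clec10a (-1.07), Itgam (-0.77) and Zeb2 (-0.63). Of the cDC2B list, the monocyte-like cDC2 subset, 7 of 10, 7 adjusted over the list alone fell while Clec12a rose by 1.02 (camera adjusted p = 3.7e-06, and adjusted p = 0.012 with an estimated correlation). The myeloid progenitor list fell in 7 of 12, 9 adjusted over the list alone (camera adjusted p = 5.1e-07, and adjusted p = 0.012 with an estimated correlation), among them the M-CSF receptor Csf1r (-1.86), with Cd34 higher. Cd34 was named after its value was seen, and Csf1r overlaps Hmgxb3. The call of Zeb2 was lost without L-cDC2 replicate 1, M-cDC2 replicate 1 or 2, CLP-cDC2 replicate 1 or 2 or CDP-cDC2 replicate 1, 2 or 3 (adjusted p up to 0.15). Itgam lost its call without L-cDC2 replicate 3, M-cDC2 replicate 1 or 2, CLP-cDC2 replicate 2 or 3 or CDP-cDC2 replicate 1 or 3 (up to 0.15). Clec12a lost its call without CLP-cDC2 replicate 1 (0.0505).

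Inflammatory mediators fell with them. Il1b, the cytokine interleukin-1 beta, stood at 59.7 ± 3.65 FPKM in CLP-cDC2 against 222 ± 38.0 in CDP-cDC2, a log2 difference of -1.87 ± 0.14 (SE, limma adjusted p = 1.4e-05). Of the cytokine and chemokine list 10 of 18, 12 adjusted over the list alone fell (camera adjusted p = 6.9e-08, and adjusted p = 0.036 with an estimated correlation), among them Cxcl16 (-1.64) and Ccl5 (-1.76). Of the list for LPS sensing and NF-kB 9 of 24, 14 adjusted over the list alone fell (camera adjusted p = 5.0e-07, and adjusted p = 0.036 with an estimated correlation), among them the inhibitor Nfkbie (-0.68). Of the Fc and complement receptors 8 of 12, 11 adjusted over the list alone fell (camera adjusted p = 7.8e-07, and adjusted p = 0.04 with an estimated correlation), among them the common gamma chain Fcer1g (-0.73) and Fcgr4 (-1.69). Of the list of inflammatory cDC2 and monocytes 6 of 11 fell, 6 adjusted over the list alone (camera adjusted p = 4.5e-04, and adjusted p = 0.036 with an estimated correlation), with Plac8 higher. The lists for type I interferon (9 of 28, 11 adjusted over the list alone, for example Ifit1 at -0.98, with Ifi205 at 1.25 the other way), interferon-gamma (7 of 23, 10 adjusted over the list alone, for example Gbp2 at -1.11) and costimulation (5 of 17, 9 adjusted over the list alone, for example Vsir at -0.83, with Lgals9 higher) passed with the preset correlation only. Their adjusted p with an estimated correlation were 0.15, 0.12 and 0.0516. The same held for MHC class II with H2-Aa, H2-Ab1 (-0.52), H2-Eb1 and Cd74 (-0.89) (4 of 15, 7 adjusted over the list alone, adjusted p = 0.14 with an estimated correlation). It held also for red pulp macrophage genes with Spic, C1qa, Adgre1 (-1.53) and Treml4 (-1.52) (4 of 9, 8 adjusted over the list alone, adjusted p = 0.14 with an estimated correlation). It held too for the immediate-early genes (7 of 23, 11 adjusted over the list alone, adjusted p = 0.18 with an estimated correlation), the C-type lectins (7 of 17, 7 adjusted over the list alone, with Clec9a, Clec12a and Cd36 higher, adjusted p = 0.18 with an estimated correlation) and the Notch2-dependent genes Cd4 and Hes1 (2 of 8, 2 adjusted over the list alone, adjusted p = 0.21 with an estimated correlation). The call of the Notch2-dependent list was lost without CDP-cDC2 replicate 3 (adjusted p = 0.095) or CLP-cDC2 replicate 1 (0.093). Ifi205 lost its call without CLP-cDC2 replicate 1 (0.0504). After quantile normalization H2-Ab1 stood at -0.11 and lost its call (adjusted p = 0.26). Plac8, Lgals9, H2-Aa, H2-Eb1, Spic and C1qa were named after their values were seen.

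In CLP-cDC2, 1021 genes rose and 889 fell against CDP-cDC2 (857 and 724 protein-coding, with 4175 genes at an unadjusted p under 0.05), and libraries did not overlap for 29.7% of genes, where chance gives 10%. Flt3, Irf4, Klf4, Esam, Clec4a4, Ly6c2, Siglech and Tcf4 did not pass, with log2 differences from -0.91 (Esam) to 1.04 (Siglech) and adjusted p from 0.066 to 0.95. Tcf4 did pass after quantile normalization, without CDP-cDC2 replicate 2, among protein-coding genes, with voom and among protein-coding genes with GC and length trends removed (limma adjusted p down to 0.027). Esam did pass with array weights and with the replicate block within each system (limma adjusted p down to 0.018). Siglech did pass without CDP-cDC2 replicate 2 and among protein-coding genes (limma adjusted p down to 0.031). Without the other-cell lists and immunoglobulin and T cell receptor genes 1006 genes rose and 889 fell, and without CDP-cDC2 replicate 3 and M-cDC2 replicate 3, 754 rose and 808 fell. The higher count dropped to 627 without CLP-cDC2 replicate 1 and 596 without CDP-cDC2 replicate 3, and both counts to 477 and 501 without CLP-cDC2 replicate 2. With only the 2 groups in the fit 312 rose and 375 fell, and without a filter on low values 576 and 491. The higher direction held 8 called lists, and 5 without CDP-cDC2 replicate 1. Calls were lost with a pseudocount of 0.1 for Zeb2, with a pseudocount of 5 for Igkj1, without a filter on low values for Car2, Ifi205, H2-Ab1, Atp5g3, Fdps, Igkj1, Itgam, Zeb2 and Clec12a, after quantile normalization for H2-Ab1, Rpl15, Rps16, Atp5c1 and Zeb2 and with only the 2 groups in the fit for Blk, Car2, Ifi205, H2-Ab1, Rpl15, Rps16, Atp5c1, Atp5g3, Msmo1, Fdps, Igkj1, Itgam, Zeb2 and Clec12a. They were also lost with array weights for Itgam, without the trend for Igkj1, with voom for Igkj1, among protein-coding genes with GC and length trends removed for Rpl15 and Rps16 and without CDP-cDC2 replicate 3 and M-cDC2 replicate 3 for Fdps, Igkj1, Itgam and Zeb2.

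**Figure D1:**
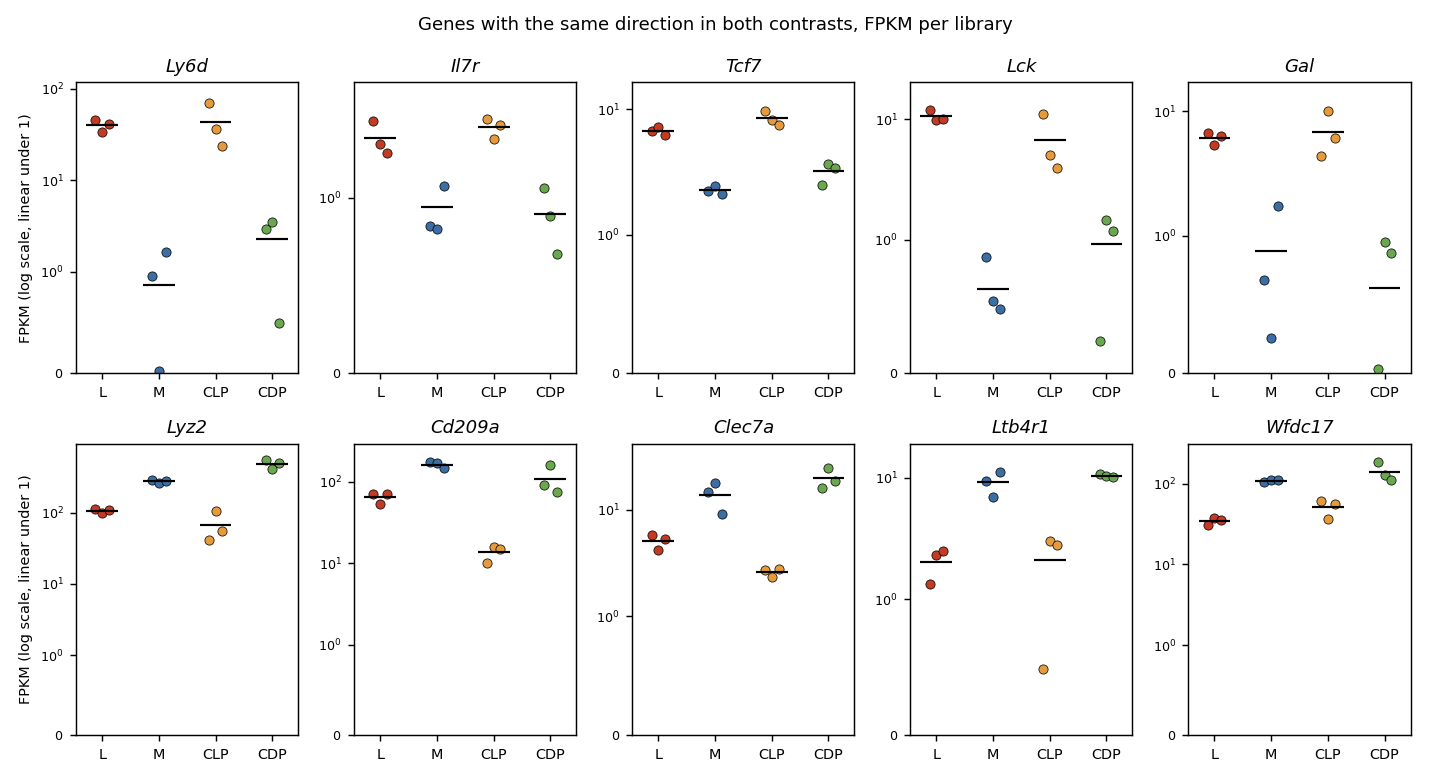
FPKM of 10 genes that moved the same way in both lineage comparisons, by group (dots are libraries, the line is their mean, and the axis is logarithmic above 1 and linear below). Ly6d, Il7r, Tcf7, Lck and Gal are higher in L-cDC2 and CLP-cDC2, and Lyz2, Cd209a, Clec7a, Ltb4r1 and Wfdc17 are higher in M-cDC2 and CDP-cDC2.

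The 2 lineage contrasts share no library, and 66 genes were called in the same direction in both. Of these, 33 rose in both L-cDC2 and CLP-cDC2, where independent lists would share 13.2 (exact hypergeometric test, one-sided p = 8.6e-07), and 33 fell in both, where 3.91 would be shared (exact hypergeometric p = 1.4e-23). Genes were counted as independent there, although Mir8119 lies inside Lck, so the hypergeometric p of these overlaps are too small. The overlap counts were not set against relabelled libraries. Without the other-cell lists and immunoglobulin and T cell receptor genes, 46 genes were shared in the same direction. Ly6d (log2 4.55 and 3.76), Lck (2.84 and 1.92), Gal (1.99 and 2.27), Igkj1 (5.48 and 1.72) and Mir8119 led the shared higher genes, with Xcl1 (3.26 in the reporter cells). Ltb4r1 (-1.74 and -2.01), Wfdc17 (-1.63 and -1.42), Lyz2 (-1.36 and -2.91), Cd209a (-1.32 and -2.85), Adgre4 (-1.26 and -2.11) and Clec7a (-1.24 and -2.49) led the shared lower genes. A further 13 genes were called in opposite directions, 9 lower in L-cDC2 and higher in CLP-cDC2 (expected 4.49, exact hypergeometric p = 0.034) and 4 the reverse (expected 11.5). Across all 14538 genes, which are not independent replicates, the log2 differences of both contrasts had a Pearson correlation of 0.0488 (p = 0.86 over 100 relabellings, two-sided) and a Spearman correlation of -0.127 (p = 0.78). Genes called in L-cDC2 against M-cDC2 moved the same way in the transferred cells in 177 of 252 cases (70.2%). Over these genes both contrasts had a Pearson correlation of 0.387, and 7 of 10 splits of the transfer libraries gave one as large in size. In the other direction, genes called in CLP-cDC2 against CDP-cDC2 had the same sign in the reporter cells in 819 of 1910 cases (42.9%). Over these genes the Pearson correlation was 0.154, and 6 of 10 splits of the reporter libraries gave one as large in size. A score of the genes called in L-cDC2 against M-cDC2 averaged 0.50 ± 0.33 in CLP-cDC2 and -0.50 ± 0.17 in CDP-cDC2 (log2 units, SD, n = 3, exact permutation p = 0.1, the smallest these samples allow, two-sided), and 0.58 and -0.58 without the other-cell lists. Between CLP-cDC2 and CDP-cDC2 its higher genes differed by 0.37 and its lower genes by -0.64. The higher genes stood at 0.0783, 0.505 and -0.0245 in CLP-cDC2 replicates 1, 2 and 3, and at 0.233, 0.313 and 0.0847 without the other-cell lists. The reverse score, from genes called between the transferred cells, averaged 0.0185 ± 0.145 in L-cDC2 and -0.0185 ± 0.1002 in M-cDC2 (exact permutation p = 0.8). With its 50 genes of smallest p in each direction it averaged 0.42 and -0.42 (exact permutation p = 0.1). The call of Igkj1 between the transferred cells was lost without L-cDC2 replicate 3, M-cDC2 replicate 1, 2 or 3, CLP-cDC2 replicate 2 or CDP-cDC2 replicate 1, 2 or 3 (adjusted p up to 0.098). The score gap of 1.01 became 1.37 without L-cDC2 replicate 3. The gap of the reverse score, 0.0371, became -0.00869 without L-cDC2 replicate 1, -0.00250 without M-cDC2 replicate 1, -0.0379 without CDP-cDC2 replicate 1 and 0.210 without CDP-cDC2 replicate 3. The Pearson correlation turned to -0.0100 without L-cDC2 replicate 1 and -0.0210 without CDP-cDC2 replicate 1, and to -0.0267 without the other-cell lists. The shared count of 66 was 37, 31 and 33 without L-cDC2 replicate 1, 2 and 3, and 34, 37 and 40 without M-cDC2 replicate 1, 2 and 3. It was 202 with array weights and 32 without a filter on low values, with 64 and 4 genes in opposite directions. The opposite count of 13 was 7, 4, 5, 5 and 6 without L-cDC2 replicate 1, 2 or 3 or M-cDC2 replicate 1 or 2, 8 and 7 without CLP-cDC2 replicate 1 or 2, and 8 without CDP-cDC2 replicate 3.

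**Figure D2:**
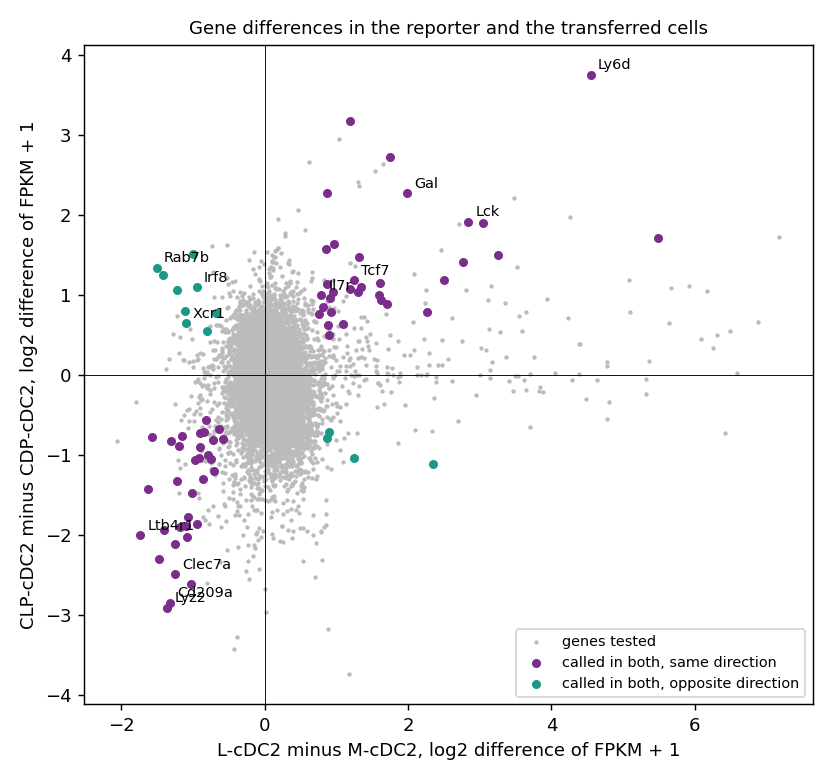
Log2 difference of each tested gene in CLP-cDC2 minus CDP-cDC2 against that in L-cDC2 minus M-cDC2, with genes called in both contrasts marked by whether they moved the same or the opposite way. The 66 genes called in the same direction lie in the lower left and upper right, and the 13 called in opposite directions in the other quadrants.

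The difference between the contrasts was tested directly. It was taken as CLP-cDC2 minus CDP-cDC2 less L-cDC2 minus M-cDC2, in log2 units, so its sign does not say in which cells a gene changed more. Gzma averaged 1.68 ± 2.26 FPKM in CLP-cDC2 and 0.73 ± 1.13 in CDP-cDC2, and its difference of contrasts was -5.81 ± 0.69 (SE, limma adjusted p = 7.5e-04), with Iglj2 at -7.15, Iglj1 at -6.22, Iglc1 at -5.94 and Iglc2 at -5.37. The call of Gzma was lost with voom on recovered reads (adjusted p = 0.0509). The B cell (median -0.94), NK cell and ILC (-2.16) and plasma cell lists (-2.74) passed with the preset correlation only, with adjusted p = 0.12, 0.067 and 0.072 with an estimated correlation. Rab7b, a small GTPase of late endosomes, was lower in L-cDC2 than M-cDC2 (6.55 ± 1.79 and 20.05 ± 0.46 FPKM) and higher in CLP-cDC2 than CDP-cDC2 (20.9 ± 4.37 and 7.84 ± 2.73 FPKM), a difference of 2.85 ± 0.33 (SE, limma adjusted p = 6.6e-04). Ifi205, an interferon-inducible DNA sensor, Gcsam, Cd24a, a surface glycoprotein, and Pdia5, a disulfide isomerase, differed by 2.67, 2.50, 2.34 and 2.29. The lists that held with an estimated correlation were cDC1 (median 1.74, 7 of 11 called, 8 adjusted over the list alone, camera adjusted p = 9.2e-10, and adjusted p = 0.02 with an estimated correlation), maturation and migration (-0.95, 11 of 23, 13 adjusted over the list alone, estimated adjusted p = 0.02), cDC2B (-1.31, 6 of 10, 8 adjusted over the list alone, estimated adjusted p = 0.027), myeloid progenitor (-1.01, 5 of 12, namely Cebpd, Csf1r, Csf2ra, Csf2rb and Lyz2, 8 adjusted over the list alone, estimated adjusted p = 0.048) and T cell (-1.26, 4 of 7, namely Trac, Trbc2, Cd247 and Cd2, 5 adjusted over the list alone, estimated adjusted p = 0.027). Quantile normalization shifted the median difference of all genes by 0.12, and values here are relative to the unshifted scale. In the cDC2B list Clec12a went the other way. Cebpd, Csf2ra, Csf2rb and Trac were named after their values were seen. In all the difference was above 0 for 346 genes and below 0 for 525, and for 177 and 283 without CDP-cDC2 replicate 3 and M-cDC2 replicate 3. These counts were 157 and 240 without L-cDC2 replicate 1, 59 and 131 without replicate 2, 130 and 192 without replicate 3, 107 and 241 without M-cDC2 replicate 2, 212 and 302 without M-cDC2 replicate 3, 176 and 336 without CLP-cDC2 replicate 1, and 122 and 302 without CLP-cDC2 replicate 2. The count above 0 alone was 190 without M-cDC2 replicate 1, 545 without CDP-cDC2 replicate 1 and 200 without CDP-cDC2 replicate 3. The 4 called lists in that direction became 7 without CLP-cDC2 replicate 3. The calls of Iglj1 and Iglc1 were each lost without L-cDC2 replicate 1, 2 or 3, M-cDC2 replicate 1, 2 or 3, CLP-cDC2 replicate 1 or 3 or CDP-cDC2 replicate 2 (adjusted p up to 0.078 and 0.08). Calls were lost without a filter on low values for Cd24a, Iglj1 and Iglc1 and without CDP-cDC2 replicate 3 and M-cDC2 replicate 3 for Iglj1 and Iglc1.

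**Figure D3:**
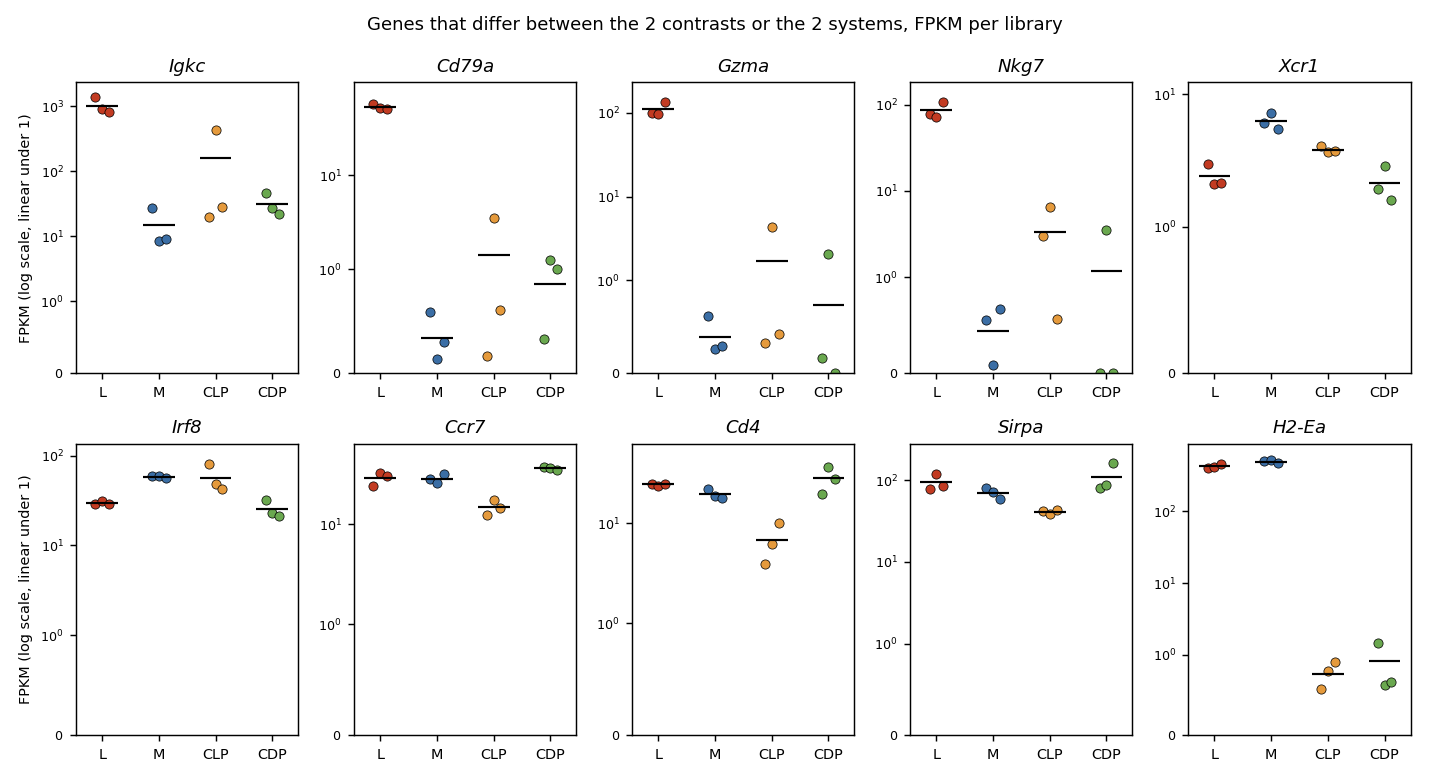
FPKM of 10 genes whose pattern differs between the reporter and the transferred cells, by group (dots are libraries, the line is their mean, and the axis is logarithmic above 1 and linear below). Igkc, Cd79a, Gzma and Nkg7 are high in L-cDC2, Xcr1 and Irf8 are lowest in L-cDC2 and CDP-cDC2, Ccr7, Cd4 and Sirpa are lowest in CLP-cDC2, and H2-Ea is near 0 in both transferred groups.

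CLP-cDC2 and L-cDC2, the pair the design asks about, were then compared directly. Mouse line, transfer and recipient differ together between these groups, as they do between CDP-cDC2 and M-cDC2. A called difference can therefore not be put down to any of them alone. H2-Ea, which encodes the E alpha chain of MHC class II (ENSMUSG00000036322, chromosome 17 from 34560933 to 34563619), stood at 0.76 ± 0.17 FPKM in CLP-cDC2 against 419 ± 22.9 in L-cDC2, a log2 difference of -7.90 ± 0.16 (SE, limma adjusted p = 9.3e-12). Other genes taken by the naming rule fell, among them Iglj2 (-5.77), Gzma (-5.67), Iglc2 (-4.90) and Cd79a (-4.74), and others rose, among them Cox6a2 (2.17), RP23-92D22.3 (2.12), Tdgf1 (2.004), the histone gene H2bu2 (1.88) and Rab7b (1.54). Of the NK cell and ILC list 10 of 12 fell (10 adjusted over the list alone, camera adjusted p = 2.3e-12, and adjusted p = 0.045 with an estimated correlation) and of the B cell list 9 of 13 (12 adjusted over the list alone, estimated adjusted p = 0.045). Of the maturation and migration list 13 of 23 fell (17 adjusted over the list alone, estimated adjusted p = 0.017), with Ccr7 at -0.92 and Relb at -1.14. The T cell (5 of 7 lower, 5 adjusted over the list alone, estimated adjusted p = 0.045) and cDC2B lists (4 of 10 lower with Clec12a and Cd300a higher, 6 adjusted over the list alone, estimated adjusted p = 0.045) fell. The cDC1 list rose (5 of 11, namely Clec9a, Irf8, Cadm1, Gcsam and Naaa, 7 adjusted over the list alone, estimated adjusted p = 0.045). The 5 called T cell genes were Trac, Trbc1, Trbc2, Cd247 and Cd2, and the lower cDC2B genes included Clec10a, Cd209a and Mgl2. Cadm1, Cd300a and Trac were named after their values were seen. A further 10 lists passed with the preset correlation only. The cell cycle list was higher in 13 of 34 members (23 adjusted over the list alone, adjusted p = 0.13 with an estimated correlation). In all 623 genes were higher and 919 lower in CLP-cDC2 (3922 at an unadjusted p under 0.05), with no overlap of libraries for 35.8% of genes, where chance gives 10%. Without CDP-cDC2 replicate 3 and M-cDC2 replicate 3, 1201 were higher and 1473 lower. The call of Cox6a2 was lost without L-cDC2 replicate 2 or 3 or CLP-cDC2 replicate 1 (adjusted p up to 0.088). The counts were 349 and 525 without L-cDC2 replicate 1, 133 and 370 without replicate 2, 283 and 504 without replicate 3, 268 and 594 without CLP-cDC2 replicate 1. The higher count alone was 359 and 368 without CLP-cDC2 replicate 2 and 3 and 1005 without CDP-cDC2 replicate 3. Calls were lost without a filter on low values for Cox6a2.

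CDP-cDC2 against M-cDC2, the corresponding pair of myeloid origin, also differed in H2-Ea, at 0.92 ± 0.48 FPKM in CDP-cDC2 and 487 ± 25.1 in M-cDC2, a log2 difference of -8.02 ± 0.16 (SE, limma adjusted p = 7.8e-12). H2-Q2, a class I gene with close paralogs, stood at 1.46 against 35.5 FPKM (-3.89). Hebp1, a heme-binding protein gene that overlaps 4 others, stood at 0.45 against 13.8 (-3.35), the microRNA gene ENSMUSG00002076479 inside Eif3j2 at -2.27 in log2 units and Mmp9, a gelatinase, at -1.97. The RNA export factor Alyref (2.03), the GTPase Arf6 (2.03), the AP-1 member Jund (1.92), the protease Adamdec1 (1.85) and Mir7654 inside Arglu1 (1.84) were highest in CDP-cDC2 by the same rule. Of the cDC1 list 6 of 11 fell (8 adjusted over the list alone, adjusted p = 0.06 with an estimated correlation), and none of the 10 lists called with the preset correlation held with an estimated one. In all 236 genes were higher and 139 lower in CDP-cDC2 (2929 at an unadjusted p under 0.05), with no overlap of libraries for 24.4% of genes, where chance gives 10%. Of the called genes 62.9% were higher, and 50.4% after quantile normalization. With only the 2 groups in the fit 13 were higher and 34 lower, without a filter on low values 40 and 63, and with array weights 1194 and 828. Without CDP-cDC2 replicate 3 and M-cDC2 replicate 3, 37 were higher and 62 lower. The call of Alyref was lost without L-cDC2 replicate 2 or 3, M-cDC2 replicate 2 or 3, CLP-cDC2 replicate 1, 2 or 3 or CDP-cDC2 replicate 2 or 3 (adjusted p up to 0.18). Arf6 lost its call without L-cDC2 replicate 1, 2 or 3, M-cDC2 replicate 2 or 3, CLP-cDC2 replicate 1, 2 or 3 or CDP-cDC2 replicate 2 or 3 (up to 0.17). Jund lost its call without L-cDC2 replicate 1, 2 or 3, M-cDC2 replicate 1, 2 or 3, CLP-cDC2 replicate 1, 2 or 3 or CDP-cDC2 replicate 2 or 3 (up to 0.17). Adamdec1 lost its call without M-cDC2 replicate 2 (0.057). The counts were 70 and 65 without M-cDC2 replicate 1, 26 and 48 without replicate 2, 39 and 75 without replicate 3 and 80 and 90 without CDP-cDC2 replicate 3. The higher count alone was 116, 143 and 113 without L-cDC2 replicate 1, 2 and 3, 123 without CDP-cDC2 replicate 1 and 415 without CDP-cDC2 replicate 2. The 6 lists called lower became 3 without CDP-cDC2 replicate 1. Calls were lost with a pseudocount of 0.1 for Jund and Adamdec1, with a pseudocount of 5 for Jund, without a filter on low values for Alyref, Arf6, Jund and Adamdec1, after quantile normalization for Alyref, Arf6 and Jund and with TMM factors for Alyref, Arf6 and Jund. They were also lost with only the 2 groups in the fit for Alyref, Arf6 and Jund, without the trend for Alyref, Arf6 and Jund, with voom for Adamdec1 and without CDP-cDC2 replicate 3 and M-cDC2 replicate 3 for Alyref, Arf6, Jund and Adamdec1.

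Whole-transcriptome similarity was measured by correlation and distance of log2(FPKM + 1) over the 14538 genes. The mean Pearson correlation of L-cDC2 libraries with CLP-cDC2 libraries was 0.950 and with CDP-cDC2 libraries 0.947, and that of M-cDC2 libraries was 0.961 and 0.962, over 9 pairs each. L-cDC2 and M-cDC2 correlated at 0.962 and CLP-cDC2 and CDP-cDC2 at 0.951, and libraries of one group at 0.965 to 0.981. All 6 transfer libraries lay nearer to M-cDC2 than to L-cDC2. The Euclidean distance to L-cDC2 less that to M-cDC2 averaged 8.63 ± 3.37 log2 units in CLP-cDC2 and 11.0 ± 7.34 in CDP-cDC2 (SD, n = 3), a difference that did not pass (exact permutation p = 0.6, two-sided, smallest possible 0.1). Without the other-cell lists and immunoglobulin and T cell receptor genes these values were 2.003 and 1.67, and without L-cDC2 replicate 2 that of CLP-cDC2 was 1.84. That of CDP-cDC2 was 6.64 without L-cDC2 replicate 1, 16.9 without CDP-cDC2 replicate 3 and M-cDC2 replicate 3, and 18.0 and 6.73 with a pseudocount of 0.1 and 5. Among protein-coding genes the values were 4.11 in CLP-cDC2 and 4.05 in CDP-cDC2, and 4.32 and 6.12 with GC and length trends removed as well. The first 3 principal components held 25.9%, 22.01% and 15.98% of the variance. On the first, the L-cDC2 libraries lay between -40.5 and -31.3 and the CLP-cDC2 libraries between 21.1 and 28.3. On the second, both lay above 0, the CDP-cDC2 libraries between -50.6 and -18.4 and the M-cDC2 libraries between -5.11 and 5.62. M-cDC2 replicate 3 (5.62) lay above L-cDC2 replicate 2 (3.02) there, so L-cDC2 and M-cDC2 overlapped on it.

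**Figure D4:**
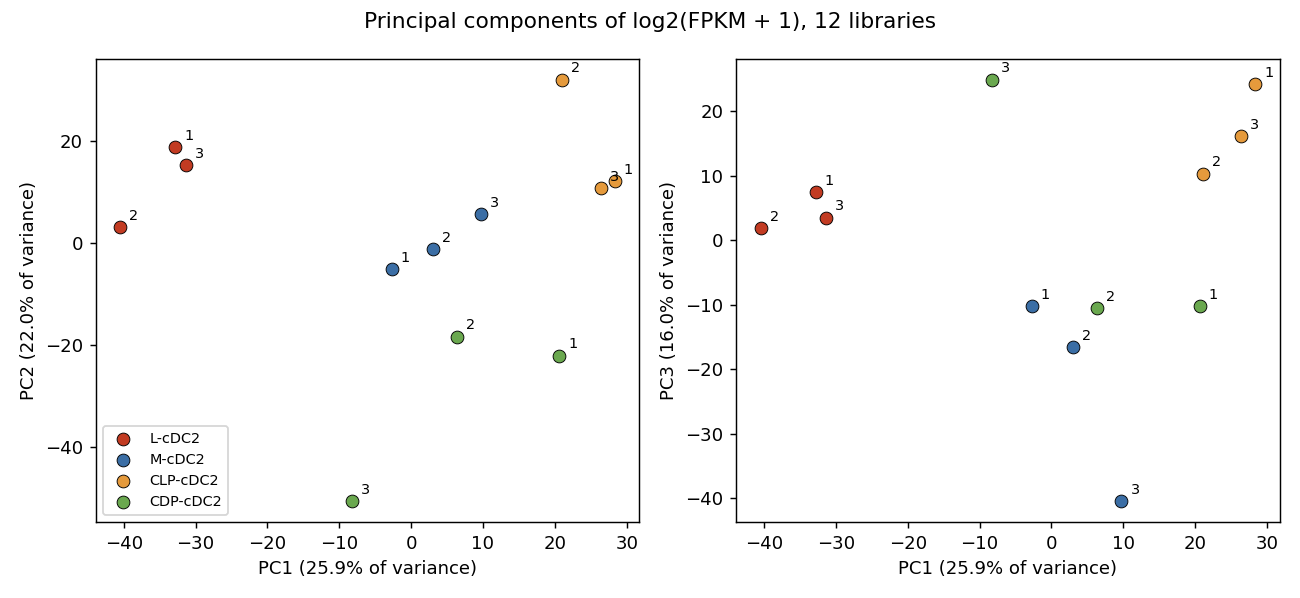
Principal components of log2(FPKM + 1) over the tested genes, 1 point per library and 1 colour per group, with the share of variance on each axis. L-cDC2 lie at the negative end of the first component, at -40.5 to -31.3, and CDP-cDC2 replicate 3 at the negative end of the second, at -50.6.

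**Figure D5:**
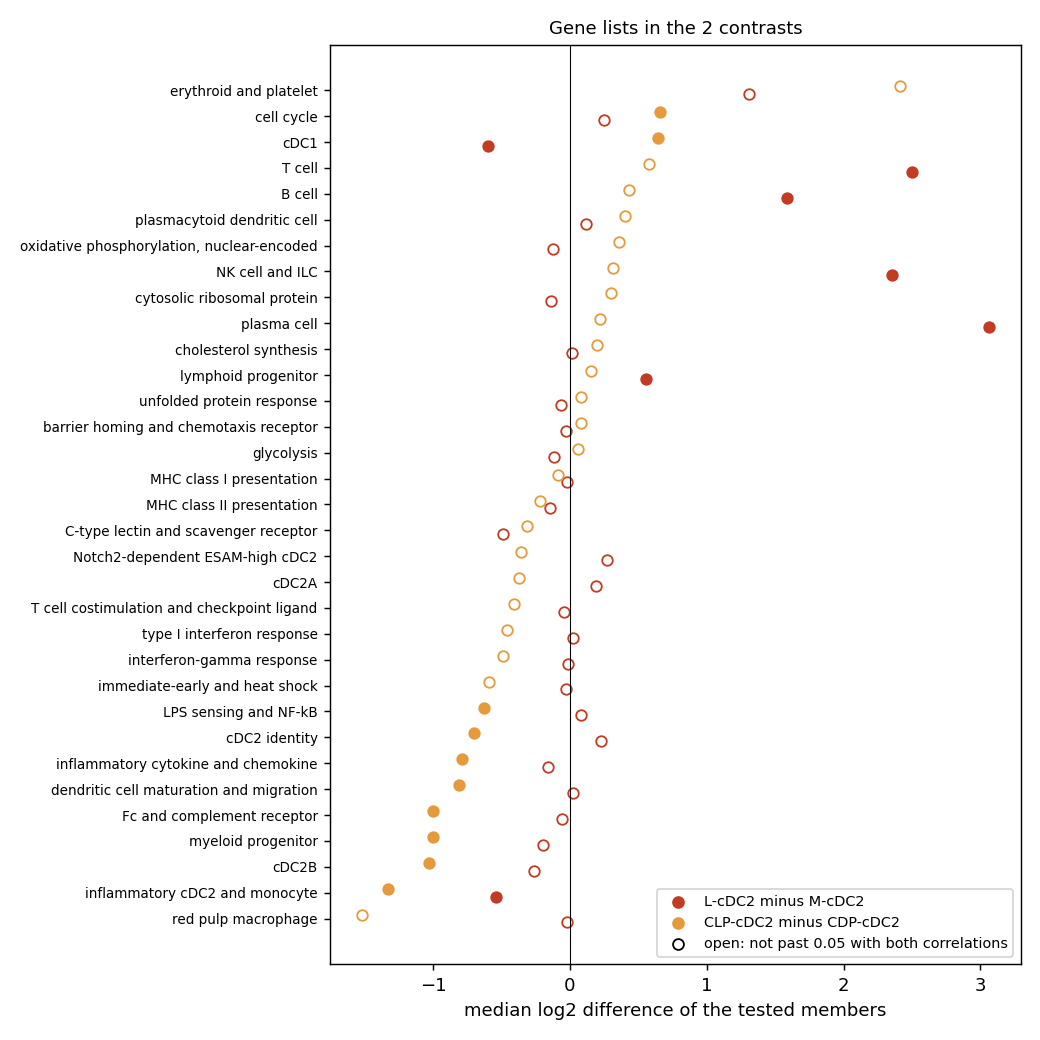
Median log2 difference of the members of each gene list in L-cDC2 minus M-cDC2 and in CLP-cDC2 minus CDP-cDC2, where a filled point passed an adjusted p of 0.05 in camera with both the preset and the estimated correlation. In L-cDC2 minus M-cDC2, 7 lists are filled, and in CLP-cDC2 minus CDP-cDC2, 10.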

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

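All tests in this part of explanations and of other splits of the libraries were chosen only after the results were seen, while the test of the difference between the contrasts was planned.

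The first pattern is the rise of B cell, plasma cell, NK cell and T cell genes in L-cDC2, led by Igkc (1023 FPKM), Gzma (110.0), Nkg7 (85.8) and Cd79a (53.5). Against T cells or their RNA as the only source of the T cell genes, the summed Cd3d, Cd3e and Cd3g rose from 0.418 ± 0.280 to 1.64 ± 0.192 FPKM, only 7.94% of the increase of Trbc1 and Trbc2 (0.452 ± 0.735 to 15.8 ± 5.13, SD, n = 3). The Cd3 sum itself did rise, and the ratio of these genes in T cells was not measured here. Some T cell RNA is therefore not excluded. On lymphoid origin as a cause of equal size in both systems, the difference between the contrasts lay below 0 for each of the 4 whole lists by fry, which tests whether a list moves on balance one way (adjusted p at most 0.0013). Set against other genes by camera with an estimated correlation, the T cell list kept its call there (adjusted p = 0.027) and the B cell, NK cell and plasma cell lists did not (0.12, 0.067 and 0.072). These 4 lists were picked for their rise in L-cDC2, which enters the difference with a minus sign. That choice favours values below 0, so neither test is independent support against lymphoid origin. Of the immunoglobulin variable segments 39 of 63 were called higher in L-cDC2 than in M-cDC2 and 0 lower. A state of cDC2, which do not make antibodies, would not raise these segments as a set. The values argue against such a state as the only source of the immunoglobulin genes, though rearranged transcripts were not identified. For the other genes, B cells, plasma cells and NK cells, or their RNA, in the tdTomato-positive sort cannot be told apart from a state of L-cDC2 in reporter mice. Of the members of the B cell, plasma cell and NK cell lists 85.4% (35 of 41, 4 of them also in another list) lay higher in every L-cDC2 library than in every M-cDC2 library. By list these were 17 of 17 B cell, 6 of 10 plasma cell and 12 of 14 NK cell and ILC members. Of the T cell list 75% (12 of 16) did so too. That list was not shown to be silent in NK cells, so its share does not count against such cells. The labels give no markers that would remove B cells, plasma cells or NK cells.

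The second pattern is the cDC1 list, lower in L-cDC2 than in M-cDC2 with several members higher in CLP-cDC2 than in CDP-cDC2. Against lymphoid origin as a cause of the same change in both systems, the whole list differed between the contrasts (median 1.74, camera adjusted p = 0.0197 with an estimated correlation), a value of the planned test in which the pattern was seen. Against trends with GC content and gene length, 100% of the members called lower in L-cDC2 (5 of 5) were still called among protein-coding genes with those trends removed, for example Irf8 from -0.95 ± 0.21 to -1.12 ± 0.20 (log2, SE). Of all protein-coding genes called in L-cDC2 minus M-cDC2, 97.5% (158 of 162) were kept too, so this share is not particular to cDC1 genes. Unequal shares of cDC1 in the sorted cells cannot be told apart from a change of these genes within cDC2. A single source would keep its genes in 1 ratio, but the log2 differences of the 11 tested members had an SD of up to 80.6% of their median (0.45 against -0.60 and 0.52 against 0.65), and levels within cDC2, not known here, may blur such a ratio (4 of the 12 genes are also in another list).

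Only 1 of 100 splits of the libraries, the real one, gave as many genes for the difference between the contrasts (871, highest other 488). That share is under 0.05, but the other splits, drawn at random from those possible, had a median of 0 called genes. Most of them mix groups that differ, which widens the spread within groups and lowers the count. The share therefore does not exclude chance, nor a spread between samples that may be technical. For the other comparisons 10 splits are too few for a share under 0.05. The real split, 1 of the 10, gave 252 called genes for L-cDC2 minus M-cDC2 (highest other 2), 1910 for CLP-cDC2 minus CDP-cDC2 (highest other 0), 1542 for CLP-cDC2 minus L-cDC2 (highest other 1) and 375 for CDP-cDC2 minus M-cDC2 (highest other 0).

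By limma's test of the difference between the contrasts (CLP-cDC2 minus CDP-cDC2 less L-cDC2 minus M-cDC2, log2 units), 346 genes lay above 0 and 525 below, a sign that does not say where a gene changed more. Named genes had adjusted p from 9.3e-05 to 0.049. B cell and plasma cell genes below 0 were Iglj1 (-6.22), Iglc1 (-5.94), Iglj2 (-7.15), Igkc (-5.12), Igkj1 (-3.77), Iglc2 (-5.37), Cd79a (-5.18), Ighg2c (-3.99) and Mzb1 (-3.15). T cell, NK cell and ILC genes below 0 were Gzma (-5.81), Nkg7 (-4.80), Trbc2 (-2.56), Cd2 (-2.18), Gzmb (-3.68), Prf1 (-2.302), Xcl1 (-1.76), Cd247 (-0.94), Gata3 (-0.80) and Ccl5 (-2.43). Other genes below 0 were ENSMUSG00002076463 (-4.93), Mefv (-2.99), Lyz1 (-2.90), Apol7c (-2.98), Lyz2 (-1.55), Cd209a (-1.53), Ocstamp (-1.60), Pla2g7 (-1.79), Il1b (-0.92), Clec7a (-1.25), Relb (-1.07), Cd40 (-0.74), Cacnb3 (-1.93), Csf1r (-1.09), Alyref (-2.74) and Arf6 (-3.12). Further genes below 0 were Jund (-3.23), Adamdec1 (-1.89), Mir7654 (-2.02), Mmp9 (-1.39), Sirpa (-1.74), Itgam (-1.24), Cd4 (-2.26), Clec10a (-1.57), Ccr7 (-1.26), Mgl2 (-2.29), Cd74 (-0.74), Nfkbie (-0.70), Treml4 (-1.37) and Hes1 (-2.296). Genes above 0 were Rab7b (2.85), Ifi205 (2.67), Aif1 (1.45), RP23-92D22.3 (1.99), Phgdh (1.60), Tdgf1 (1.76), Naaa (1.79), Xcr1 (1.75), Clec9a (1.91) and Gcsam (2.50). Further genes above 0 were Cdc20 (0.69), Cdk1 (0.98), Cd24a (2.34), Pdia5 (2.29), Irf8 (2.04), Clec12a (1.53), Cd36 (1.48) and Ccr2 (1.52). The list medians that differed were 1.74 for cDC1, -1.31 for cDC2B, -0.95 for maturation and migration, -1.01 for myeloid progenitor and -1.26 for T cell genes.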

How the results depend on the processing

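Tests among protein-coding genes, with voom, among protein-coding genes with GC and length trends removed, without CDP-cDC2 replicate 3 and M-cDC2 replicate 3, without the other-cell lists, and of gene lists under other scalings were chosen only after the results were seen. Over all alternatives, values of named genes kept direction and side of the threshold in 4477 cases, lost the call in 321, gained it in 12 and turned sign in 31, and list values kept both in 1502 cases and lost the call in 139. The values below changed, and the cause was not tested except where fewer genes, lists or libraries entered by construction. edgeR and DESeq2 on counts were not run, since the table holds FPKM with partly fractional reads behind it. Depth limits genes near the floor of 3 reads, such as Igkj4 in M-cDC2. Replicate numbers gave no clear sign of pairing the samples. Correlations of same-numbered deviations ran from -0.224 to 0.128 between L-cDC2 and M-cDC2 and from -0.0342 to 0.282 between CLP-cDC2 and CDP-cDC2. In no pair of groups did every sample correlate best with its own number, while 2 did between CLP-cDC2 and CDP-cDC2. Deviations from means of 3 libraries cannot show that samples are unpaired. The score gap is that of the L-cDC2 score between CLP-cDC2 and CDP-cDC2, and the reverse score gap that of the transferred-cell score between L-cDC2 and M-cDC2. List median, mean and test differed in sign for cholesterol synthesis, maturation and migration, and type I interferon in L-cDC2 minus M-cDC2 and for glycolysis in CLP-cDC2 minus CDP-cDC2. They also differed for cholesterol synthesis, erythroid, lymphoid progenitor, plasmacytoid and unfolded protein lists in CLP-cDC2 minus L-cDC2, and for B cell, glycolysis and NK cell lists in CDP-cDC2 minus M-cDC2, none of them called there. With a pseudocount of 0.1 the changed values were CLP-cDC2 (distance to L-cDC2 less that to M-cDC2) 12.8. With a pseudocount of 5 the changed values were score gap 0.616 and reverse score gap -3.7e-04. With no filter on low values the changed values were genes lower 35 (L-cDC2 minus M-cDC2), genes higher 576 and genes lower 491 (CLP-cDC2 minus CDP-cDC2), genes higher 80 and genes lower 175 (the difference), genes higher 293 (CLP-cDC2 minus L-cDC2), genes higher 40 and genes lower 63 (CDP-cDC2 minus M-cDC2) and genes shared in the same direction 32 and genes shared in opposite directions 4. With FPKM of at least 5 in at least 3 libraries the changed values were genes higher 84 (L-cDC2 minus M-cDC2) and reverse score gap -0.0214. After quantile normalization the changed values were Zeb2 -0.0537, Tcf4 -0.0247, Ccr7 -0.00480 and Xist -0.00828 (L-cDC2 minus M-cDC2), Flt3 -0.142 (CLP-cDC2 minus CDP-cDC2) and genes higher 134 and lists lower 3 (CDP-cDC2 minus M-cDC2). With TMM factors the changed values were Ccr7 -0.0329 (L-cDC2 minus M-cDC2) and Flt3 -5.5e-04 (CLP-cDC2 minus CDP-cDC2). With only the 2 groups compared in the fit the changed values were genes higher 312 and genes lower 375 (CLP-cDC2 minus CDP-cDC2), genes higher 13 and genes lower 34 (CDP-cDC2 minus M-cDC2) and genes shared in opposite directions 7. With array weights the changed values were genes higher 538, genes lower 300, Zeb2 -0.0635 and Xist -0.0600 (L-cDC2 minus M-cDC2), Flt3 -0.137 and Irf4 0.0521 (CLP-cDC2 minus CDP-cDC2), genes higher 962 and genes lower 1082 (the difference), genes higher 1127 (CLP-cDC2 minus L-cDC2), genes higher 1194 and genes lower 828 (CDP-cDC2 minus M-cDC2) and genes shared in the same direction 202 and genes shared in opposite directions 64. With the replicate block shared by all 4 groups the changed values were genes higher 163 and genes lower 314 (the difference) and genes higher 94 and genes lower 92 (CDP-cDC2 minus M-cDC2). Without the trend the changed values were genes higher 204 (the difference). With the 50 genes of smallest p in each direction the changed values were reverse score gap 0.837. With an estimated correlation in camera the changed values were lists lower 2 (L-cDC2 minus M-cDC2), lists higher 2 and lists lower 8 (CLP-cDC2 minus CDP-cDC2), lists higher 1 and lists lower 4 (the difference), lists higher 1 and lists lower 5 (CLP-cDC2 minus L-cDC2) and lists higher 0 and lists lower 0 (CDP-cDC2 minus M-cDC2). With fry the changed values were lists lower 4 (L-cDC2 minus M-cDC2) and lists lower 3 (CDP-cDC2 minus M-cDC2). Among protein-coding genes the changed values were genes higher 110 (L-cDC2 minus M-cDC2), genes higher 461 (CDP-cDC2 minus M-cDC2) and reverse score gap -0.0174, Pearson correlation of the contrasts -0.0234 and CLP-cDC2 (distance to L-cDC2 less that to M-cDC2) 4.11. With voom on recovered reads the changed values were genes higher 477 (CDP-cDC2 minus M-cDC2). Among protein-coding genes with GC and length trends removed the changed values were genes higher 106, genes lower 107, Zeb2 -0.0753, Tcf4 -0.0127 and Ccr7 -0.00336 (L-cDC2 minus M-cDC2), Clec4a4 -0.191 (CLP-cDC2 minus CDP-cDC2), genes higher 776 (the difference), genes higher 1146 (CLP-cDC2 minus L-cDC2), genes higher 393 and genes lower 296 (CDP-cDC2 minus M-cDC2) and CLP-cDC2 (distance to L-cDC2 less that to M-cDC2) 4.32. Both the set of genes and the values differ there, and the set of genes alone gave the 110, 461 and 4.11 above. Without CDP-cDC2 replicate 3 and M-cDC2 replicate 3 the changed values were Zeb2 -0.0573 and Xist -0.184 (L-cDC2 minus M-cDC2), Flt3 -0.0313 and Irf4 0.0925 (CLP-cDC2 minus CDP-cDC2), genes higher 177 and genes lower 283 (the difference), genes higher 1201 and genes lower 1473 (CLP-cDC2 minus L-cDC2) and genes higher 37 and genes lower 62 (CDP-cDC2 minus M-cDC2). Without the other-cell lists and immunoglobulin and T cell receptor genes the changed values were genes higher 85 (L-cDC2 minus M-cDC2) and genes shared in opposite directions 6, Pearson correlation of the contrasts -0.0267, CLP-cDC2 (distance to L-cDC2 less that to M-cDC2) 2.003 and CDP-cDC2 (distance to L-cDC2 less that to M-cDC2) 1.67. With the replicate block shared by all 4 groups, named genes with an adjusted p no longer under 0.05 were H2-DMb1 (0.093) and Il7r (0.064) in L-cDC2 minus M-cDC2, Trbc1 (0.0547), Igkj1 (0.066), Itgam (0.073) and Zeb2 (0.082) in CLP-cDC2 minus CDP-cDC2 and Alyref (0.091), Arf6 (0.09) and Jund (0.061) in CDP-cDC2 minus M-cDC2. With the replicate block within each system they were Mgl2 (0.06), H2-DMb1 (0.15) and Il7r (0.13) in L-cDC2 minus M-cDC2 and Igkj1 (0.064) and Zeb2 (0.058) in CLP-cDC2 minus CDP-cDC2, and Esam (0.025) in CLP-cDC2 minus CDP-cDC2 passed. Among all genes taken by the naming rule, 11 calls were lost with the shared block and 8 with the block within each system. Those not listed above were of genes not reported here. The blocks changed no other call of the reported genes they were run on. Leaving out 1 library at a time gave these ranges. L-cDC2 minus M-cDC2, genes higher ran from 78 to 209. L-cDC2 minus M-cDC2, genes lower ran from 18 to 80. CLP-cDC2 minus CDP-cDC2, genes higher ran from 477 to 1073. CLP-cDC2 minus CDP-cDC2, genes lower ran from 501 to 907. The difference, genes higher ran from 59 to 545. The difference, genes lower ran from 131 to 695. CLP-cDC2 minus L-cDC2, genes higher ran from 133 to 1005. CLP-cDC2 minus L-cDC2, genes lower ran from 370 to 1340. CDP-cDC2 minus M-cDC2, genes higher ran from 26 to 415. CDP-cDC2 minus M-cDC2, genes lower ran from 48 to 171. Genes shared in the same direction ran from 31 to 75. Genes shared in opposite directions ran from 4 to 14. Score gap ran from 0.886 to 1.37. Reverse score gap ran from -0.0379 to 0.210. Pearson correlation of the contrasts ran from -0.0210 to 0.149. CLP-cDC2 (distance to L-cDC2 less that to M-cDC2) ran from 1.84 to 11.4. CDP-cDC2 (distance to L-cDC2 less that to M-cDC2) ran from 6.64 to 15.2. L-cDC2 minus M-cDC2, lists lower ran from 8 to 14. CLP-cDC2 minus CDP-cDC2, lists higher ran from 5 to 9. The difference, lists higher ran from 4 to 7. CDP-cDC2 minus M-cDC2, lists lower ran from 3 to 6. Log2 differences that turned sign, none called, ranged for Flt3 in CLP-cDC2 minus CDP-cDC2 from -0.0734 to 0.150, Irf4 in CLP-cDC2 minus CDP-cDC2 from -0.173 to 0.0925, Ccr7 in L-cDC2 minus M-cDC2 from -0.0719 to 0.127, Flt3 in L-cDC2 minus M-cDC2 from -0.109 to 0.0107, Xist in L-cDC2 minus M-cDC2 from -0.184 to 0.305 and Zeb2 in L-cDC2 minus M-cDC2 from -0.0690 to 0.194.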

Other observations

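The test of chromosome segments was written before its result was seen, and the tests of the other MHC class II genes and of each chromosome were chosen only after. Between the transferred and the reporter cells, 106 genes were called in the same direction in both comparisons, 30 higher in the transferred cells (expected 10.1 for independent lists) and 76 lower (expected 8.79), and 17 in opposite directions (expected 20.9). These comparisons share no library. H2-Ea averaged 419 ± 22.9 and 487 ± 25.1 FPKM in L-cDC2 and M-cDC2 (SD, n = 3) against 0.76 ± 0.17 and 0.92 ± 0.48 in CLP-cDC2 and CDP-cDC2, H2-Q2 33.6 and 35.5 against 0.96 and 1.46, and Hebp1 14.6 and 13.8 against 0.18 and 0.45. Rtl8c, a retrotransposon-derived gene, was lower in the transferred cells (log2 -2.22 and -1.63), and Fosb, an AP-1 member (1.16 and 1.40), and Mt1, a metallothionein (0.98 and 1.22), were higher. These 3 genes were chosen after their values were seen. Of the 106 genes 26 lie on chromosome 17, 25 of them within 20 Mb of H2-Ea, and 10 have H2 symbols. Chromosome 17 held 24.5% of the 106 against 5.46% of tested genes (exact one-sided hypergeometric test, adjusted p over 21 chromosomes = 1.3e-09), chromosome 11 18.9% against 8.14% (20 genes, adjusted p = 0.0033) and chromosome Y 2 of its 6 tested genes (adjusted p = 0.0054). On chromosomes 17 and 11, 15 and 11 of these genes lie within 50 kb of another, so they are not independent and these p are too small. On chromosome 11 they include U3 RNA genes entered more than once at the same place. An example is ENSMUSG00000119262 and ENSMUSG00002076650 (log2 -0.775 and -0.775 in CLP-cDC2 minus L-cDC2). They also include neighbouring histone genes such as H2bu2 and H2aw. Whether an excess on chromosome 11 remains with such entries counted once was not tested. Immunoglobulin variable segments were higher in L-cDC2 than in M-cDC2 in 39 of 63 cases and in CLP-cDC2 than in CDP-cDC2 in 0 of 63, with 38 below 0 in the difference and 42 lower in CLP-cDC2 than in L-cDC2.

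Mice of the C57BL/6 background carry an H2-Ea allele that is not transcribed, while several other strains express it. A hypothesis is that the reporter line carries chromosome segments of another strain. With genes already named set aside, 100 genes called in both comparisons were left. Among them, those within 20 Mb of H2-Ea, Rosa26 or Il7r were 4.56 times as frequent as among the other tested genes (27 of 100, exact one-sided hypergeometric p = 1.5e-11). The H2-Ea region gave 23 of these (exact hypergeometric p = 1.6e-12), Rosa26 4 (p = 0.10) and Il7r 0. H2-Ea itself prompted the hypothesis, and many genes of its region lie close together, so these p are too small. Hebp1 lies 22.1 Mb from Rosa26, outside each of these windows, so the test does not bear on it and the hypothesis stays limited to the region of H2-Ea and H2-Q2. The test does not cover the genes called on chromosome 11 either, which holds none of these loci and where repeated entries raise the count. Against lower activity of all MHC class II genes in the transferred cells, the 15 tested members of that list, which does not hold H2-Ea, had a median log2 difference of -0.12 (SD 0.30) in CLP-cDC2 minus L-cDC2 and 0.12 in CDP-cDC2 minus M-cDC2. Transfer, recipient and mouse line differ together between the systems, so other differences between them stay open and were not tested.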
